A study of Rattus norvegicus with 15 samples.

How the data were processed

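Bulk RNA sequencing was carried out on mammary tumours of Fischer rats given the carcinogen N-nitroso-N-methylurea (NMU). Per the labels' protocols, the midkine group received recombinant protein at 300 ug/kg, 3 times a week, for 2 weeks before a first intraperitoneal dose of NMU (50 mg/kg) and for another 2 weeks before a second. A piece of each tumour was ground, RNA was isolated with a spin-column kit, and 3000 ng per sample went to a sequencing company. That company made libraries after poly(A) selection and sequenced 150-bp read pairs on an Illumina HiSeq instrument, per the labels' protocols.

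The authors deposited 1 table of whole-number read counts for 17463 gene symbols in 15 libraries, with no normalization, per the file headers and the values. The submitters' processing notes name the genome build rn6. The aligner's version, the counting mode, the strand setting and the annotation are not given in the sources used here, so reads of near-identical gene copies and of overlapping or antisense genes may be split or shared in ways that these counts do not show. Symbols were compared with a gene table of the assembly GRCr8 for names only: 15570 matched a current symbol, 1545 matched an older one and 348 matched neither. No coordinates were used, since that assembly is not the build named in the notes.

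Samples were grouped by the treatment label as vehicle (6 libraries) or midkine (9 libraries) and are named by group and title number. Some titles share a number (vehicle 2-1 and 2-2; midkine 3-1 and 3-2; midkine 4-1, 4-2 and 4-3), which could mean tumours of 1 animal, but no label says so. P-values therefore measure the spread between these libraries, part of which may lie within an animal or be technical. No label gives a sequencing date or batch. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom was at least 19.9 over genes with a mean count of at least 20.

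Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the package's expression filter by group, which left 11665, and library sizes were scaled by trimmed mean of M-values. Midkine was compared with vehicle by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are CPM, read counts scaled to a common library size, after that scaling, and raw CPM where so named are scaled by the deposited total alone. A list of genes is scored as the mean log2 CPM (prior count 2) of its measured members.

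The fixed lists numbered 34 and held markers of epithelial, connective tissue, vessel, fat, muscle, nerve, blood and immune cells, together with pathways from midkine receptors and lipid synthesis to proliferation, repair, stress and interferon response. The 30 lists with at least 5 measured members were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The same test with an estimated correlation, fry, and an exact permutation of the mean level over all splits of the libraries into 6 and 9 were run beside it. Expression distances were Euclidean over log2 CPM of all genes kept. The share of squared distance between groups was tested exactly, one-sided, over the same splits. The difference of mean distance to the group centroid was tested over them two-sided, with each library's distance to its own group's centroid kept fixed. The similarity of libraries that share a title number was tested one-sided with 100000 permutations of the numbers within groups.

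The genes to be named were fixed by rule before the data were examined, as were the groups, the tests, the lists and most of the other settings. The rule took MDK with the measured members of the midkine list, the 12 genes per direction with the largest change among those past the threshold, filled up by smallest p (at a mean log2 CPM of at least 0 and with a symbol that is no placeholder), up to 4 members of smallest p from each list, and MKI67, SREBF1, FASN, ESR1, PGR, KRT8, KRT14, PTPRC, COL1A1, PECAM1, ADIPOQ and ACTA1. It gave 169 genes, since ADIPOQ was not kept by the filter. The number per list was used as a ceiling, and 116 of the 169 were followed by name through the alternatives. Which 116 was decided after values had been seen, and some genes that the rule gives are not reported here, so the stability of directions is given over all 169. Genes named outside the rule are said to be so.

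The gene tests, camera, the treatment share, the spread and the title-number similarity were tested on simulated data, while fry and the permutation of list levels were not. In sets drawn from the means, dispersions and library sizes of the 11665 genes, 200 of them changed, the edgeR test recovered 23.5% of genes changed 2-fold, 80.0% of those changed 4-fold and 93.5% of those changed 8-fold, with 2, 5 and 7 false calls. DESeq2 1.42.0 recovered 53.0%, 87.5% and 97.0%, with 25, 28 and 30 false calls. Genes were drawn independently and with no library standing apart, once per fold, so these rates may overstate recovery in the deposited data. The centroid distance test as designed passed its threshold in 36% of 100 sets of 500 genes simulated with equal spread, because distances are shorter in the smaller group, against 6% after a correction for group size. That correction is therefore printed beside the value over 15 libraries, and all other values of that test are uncorrected.

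Other settings fixed in advance were relative log expression and upper-quartile scaling, a filter of 1 CPM in 6 libraries or of 1 count, robust shrinkage, a prior count of 0.5, the 1000 most variable genes, DESeq2, limma-voom with and without quality weights or a title-number correlation, counts summed per title number, 1 library per number, the number as a block, an epithelial covariate for single genes, 1 surrogate variable (sva 3.50.0) and leaving out each library. Settings chosen after seeing the data were leaving out 4 midkine libraries (1, 3-2, 4-2 and 5) whose median correlation with the others was under 0.95, keeping the 10 libraries with MYH4 above 50 raw CPM, leaving out each of those 10 in turn, MYH4 carriage as a covariate, the epithelial covariate for lists, DESeq2 without outlier replacement and the group-size correction. The title-number block joined vehicle and midkine libraries of the same number, although no label pairs numbers across groups. Depth limits the precision of genes with few counts per library, and the counts give no duplicate rate.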

Results

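Transcripts were counted in 15 NMU-induced rat mammary tumour libraries, 6 from vehicle-treated and 9 from midkine-treated animals. Midkine is a heparin-binding growth factor, and the study asked whether it drives age-related change and tumour formation in the mammary gland. Libraries held 4925504 to 8486523 counted reads (median 7252603) and between 13056 and 13665 genes with at least 1 count. The lowest total was that of vehicle 5.

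MYH4, a fast-fibre muscle myosin chosen after its values were seen, divided the libraries in a way that the treatment label does not. It stood at 55763 raw CPM in midkine 1 and at 72.5 to 167 raw CPM in 9 libraries, namely all 6 vehicle libraries and midkine 2, 5 and 6. In midkine 3-1, 3-2, 4-1, 4-2 and 4-3 it had at most 1 count. These 5 libraries all belong to the midkine group, and no vehicle library shared their lack of MYH4 reads. They are also all the midkine libraries of title numbers 3 and 4, the only midkine numbers with more than 1 library. If a number stands for 1 animal, the divide cannot be told apart from a difference between animals. Values within the 10 libraries that carried MYH4 reads (6 vehicle, 4 midkine) are given beside the pooled ones for the distances and for part of the lists and genes.

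**Figure D1:**
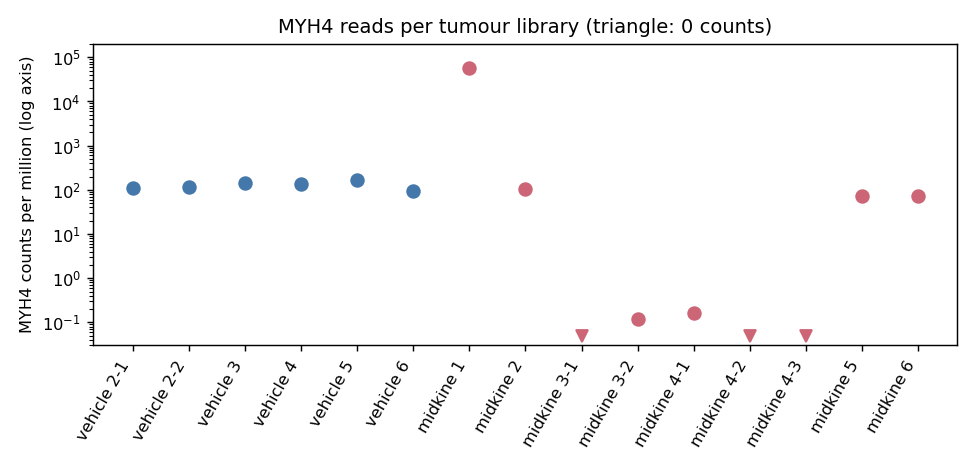
Raw MYH4 level in CPM (log axis) in each of the 15 tumour libraries, blue for vehicle and red for midkine, with triangles for libraries of 0 counts. Midkine 1 lies at 55763, 9 libraries lie between 72.5 and 167, and 5 midkine libraries lie at or below 0.167.

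MDK, the gene of the administered factor, had similar mean levels in both groups: 222 ± 101 CPM (SD, n = 6) in vehicle and 233 ± 185 CPM (SD, n = 9) in midkine tumours. The log2 fold change was 0.07 (SE 0.48, adjusted p = 0.980). Midkine 5 had the highest MDK level, 674 CPM, and vehicle 2-1 the lowest, 54.4 CPM. PTN, which encodes the related factor pleiotrophin, stood at 403 ± 156 CPM in vehicle and 251 ± 143 CPM in midkine tumours (log2 fold change -0.69, SE 0.35, adjusted p = 0.541).

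None of the 17 measured genes of midkine ligands and receptors passed the threshold over all genes or adjusted over the list alone. The heparan sulfate proteoglycan SDC2 stood at 172 ± 62.9 and 127 ± 26.5 CPM (log2 fold change -0.43, SE 0.21), and the glypican GPC2 had a log2 fold change of -0.72 (SE 0.45). The integrin ITGA4 had a log2 fold change of 1.16 (SE 0.69), the endocytic receptor LRP1 of 0.35 (SE 0.31), NOTCH2 of 0.51 (SE 0.36) and SDC1 of 0.36 (SE 0.40). Without midkine 5, which held 1134 CPM of LRP1 against 366 CPM in the next midkine library, LRP1 had 0.00 (SE 0.16). Without midkine 3-2 NOTCH2 had 0.25 (SE 0.30) and SDC1 0.10 (SE 0.36), and without midkine 4-2 ITGA4 had 0.62 (SE 0.60). The receptors ALK, LTK and PTPRZ1 had values of -0.42 (SE 0.56), 0.04 (SE 0.56) and 0.28 (SE 0.39). ALK had 0.05 (SE 0.57) without vehicle 4, and PTPRZ1 had 0.05 (SE 0.36) without midkine 2. LTK ran from -0.18 without midkine 4-1 to 0.66 without vehicle 5. SDC3 (-0.38), SDC4 (-0.12), ITGA6 (-0.17), ITGB1 (0.16), LRP2 (0.18) and NCL (0.09) made up the rest. Without vehicle 2-1 GPC2 had -0.44 (SE 0.46), and without vehicle 6 SDC2 had -0.28 (SE 0.21). The list's median log2 fold change was 0.07 and its mean level difference -0.07, with camera pointing down (adjusted p = 0.569). Without midkine 1 camera pointed up (adjusted p = 0.869). Within the 10 libraries that carried MYH4 reads the mean level difference was -0.15. It ranged there from -0.25 without midkine 2 to 0.02 without midkine 1.

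Within the 10 libraries that carried MYH4 reads the MDK log2 fold change was 0.59 (SE 0.54) and that of PTN -0.81 (SE 0.43). The direction of MDK turned when vehicle 2-1 (-0.13), vehicle 6 (-0.015) or midkine 5 (-0.32) was left out.

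**Figure D2:**
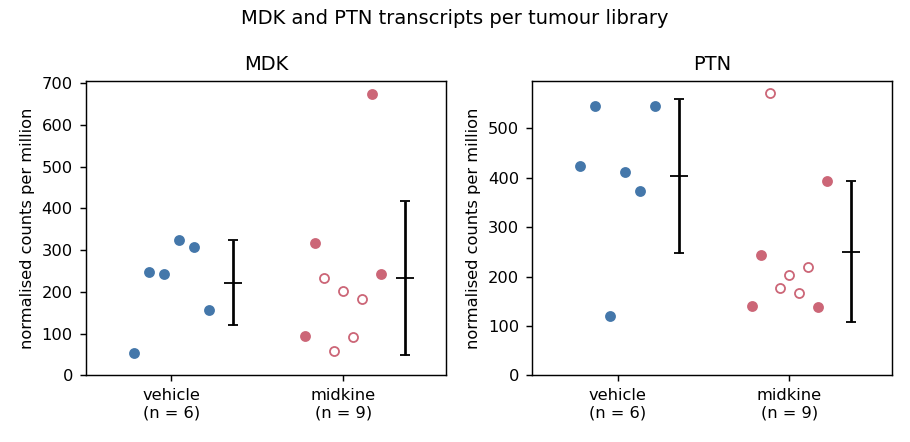
MDK (left) and PTN (right) in normalised CPM per library, with blue points for vehicle (n = 6), red points for midkine (n = 9), open red points for midkine libraries with at most 1 MYH4 count, and bars for mean ± SD. Midkine 5 lies at 674 CPM of MDK, above the 317 CPM of midkine 2.

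At the level of single genes, no transcript passed the threshold in either direction among 11665 tested (smallest adjusted p = 0.399). The genes of smallest p that were higher in midkine tumours included ANGPTL4, which encodes an inhibitor of lipoprotein lipase, at 12.6 ± 5.56 CPM in vehicle (SD, n = 6) and 53.5 ± 37.1 CPM in midkine tumours (SD, n = 9). They also included the growth factor gene IGF1 (9.66 ± 3.27 and 40.9 ± 36.0 CPM), the myeloid nuclear antigen gene MNDA (4.63 ± 1.87 and 18.5 ± 11.1 CPM), the transcription repressor ZEB2 (5.68 ± 3.42 and 24.4 ± 19.7 CPM) and the matrix gene OLFML2B (16.4 ± 6.48 and 44.3 ± 18.8 CPM). On the lower side stood FGF1 (70.6 ± 43.4 and 22.6 ± 7.37 CPM), the matrix gene TINAGL1 (230 ± 75.4 and 113 ± 39.1 CPM), the co-activator CITED4 (155 ± 105 and 47.2 ± 23.6 CPM) and the calmodulin-binding gene NRGN (68.9 ± 102 and 4.81 ± 1.27 CPM).

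Log2 fold changes among the 12 higher genes ran from 0.55 (SE 0.13) for FGB to 2.83 (SE 0.71) for AQP3, and ADAM19, ADORA2A, RELT, SEMA5B and ALB lay between. Among the 12 lower genes they ran from -0.50 (SE 0.14) for PRSS8 to -3.84 (SE 0.86) for NRGN. NRGN stood at 234 and 159 CPM in vehicle 2-1 and 2-2. The other vehicle libraries held at most 7.93 CPM and the midkine libraries at most 6.99 CPM. Its medians were 6.57 and 5.21 CPM. Its value was -2.90 (SE 0.79) without vehicle 2-1 and -0.76 (SE 0.69) with the title number as a block. That block pairs vehicle with midkine libraries by number, so it does not correct for tumours of 1 animal alone. The epithelial sodium channel genes SCNN1B (-1.23, SE 0.32) and SCNN1G (-0.98, SE 0.29), the peptide receptor VIPR1 (-1.24, SE 0.33), the junction gene CGNL1 (-0.68, SE 0.19), SMAD1 (-0.77, SE 0.22), BICDL2 (-0.74, SE 0.20) and PLEKHH1 (-0.70, SE 0.21) were also on this side. None of these 24 passed the edgeR threshold. Midkine and vehicle libraries did not overlap for 2 genes, fewer than the 4.66 that chance gives over 11665 genes (0.040% per gene). With 1 library left out, 52 of the 116 genes followed by name turned or moved by over 1.5 times in log2 fold change. They included 21 without midkine 3-2, 14 without midkine 1 and 13 without midkine 4-2.

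An unadjusted p under 0.05 was found for 1178 genes, 929 of them higher and 249 lower in midkine tumours. Evenly spread p-values would give 583, but genes that vary together can give more. Of 100 splits of the libraries into 6 and 9, the real one included, 15 gave at least 1178. DESeq2 called 86 genes higher and 6 lower, among them ANGPTL4 (log2 fold change 2.12, SE 0.46, adjusted p = 0.00887), FGF1 (-1.63, SE 0.37, adjusted p = 0.0118) and IGF1 (2.10, SE 0.47, adjusted p = 0.0118). Of the called genes that edgeR also tested, 30 had their highest level in midkine 4-2, 22 in midkine 3-2 and 11 in midkine 5. Within the 10 libraries that carried MYH4 reads edgeR again called no gene, 1188 lay at an unadjusted p under 0.05, and the log2 fold change was 1.95 (SE 0.45) for ANGPTL4, 2.53 (SE 0.48) for IGF1 and -1.71 (SE 0.54) for FGF1. limma-voom also called 0 genes, put 602 at an unadjusted p under 0.05 and made 46.8% of them higher, against 78.9% with edgeR.

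Marker genes of connective tissue, vessel and immune cells stood higher in the midkine tumours and epithelial markers lower when each list was compared with all other genes. Of 30 lists tested, 15 passed at the preset correlation, 10 higher and 5 lower. No member gene passed over all genes, 60 passed when adjusted over the list alone, and no list passed with an estimated correlation (smallest adjusted p = 0.413), by fry (smallest adjusted p = 0.432) or by exact permutation of the mean level (smallest adjusted p = 0.309). Of the 60, 18 belonged to the skeletal muscle list, which did not itself pass, and some to other lists that did not pass or were not tested. The estimated correlation had a median of 0.523 and lay above the preset 0.01 for 29 of the 30 lists. List p-values by camera below use the preset unless an estimated correlation is named.

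The macrophage list had all 16 measured members higher in midkine tumours, with a mean level of 4.28 ± 0.53 log2 CPM in vehicle (SD, n = 6) and 5.12 ± 0.76 in midkine (SD, n = 9). Its adjusted p was 2.95e-08 by camera and 0.413 with an estimated correlation. The scavenger receptors MSR1 and CD163 had log2 fold changes of 1.53 (SE 0.51) and 1.45 (SE 0.58), the lysozyme gene LYZ2 of 1.46 (SE 0.59) and the integrin ITGAM of 1.46 (SE 0.56). These 4 genes had 0.78 (SE 0.52), 0.85 (SE 0.67), 0.03 (SE 0.38) and 0.20 (SE 0.46) within the 10 libraries that carried MYH4 reads. The T and NK cell list had 18 of 19 members higher and 12 past the threshold adjusted over the list alone, at 2.23 ± 0.44 and 3.26 ± 1.66 log2 CPM (adjusted p = 4.85e-07 by camera, adjusted p = 0.424 with an estimated correlation). The cytotoxic gene PRF1 had a log2 fold change of 3.07 (SE 0.88), CD3G of 2.74 (SE 0.89) and the regulatory T cell factor FOXP3 of 0.86 (SE 0.26). These 3 genes stood at 0.78 (SE 0.50), 0.39 (SE 0.47) and 0.43 (SE 0.21) within the 10 libraries. Without midkine 4-2 PRF1 stood at 2.12 (SE 0.65), CD3G at 1.74 (SE 0.66) and LYZ2 at 0.83 (SE 0.44).

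Inflammatory cytokine genes were higher for all 14 measured members, 9 of them past the threshold adjusted over the list alone, and the list stood at 2.74 ± 0.41 and 4.01 ± 1.67 log2 CPM (adjusted p = 2.90e-05 by camera, adjusted p = 0.413 with an estimated correlation). The neutrophil-attracting chemokines CXCL2 and CXCL3 had log2 fold changes of 7.39 (SE 2.19) and 7.03 (SE 2.11). Midkine 3-2 held 1059 CPM of CXCL2 against 4.81 CPM in the next midkine library. Without it they stood at 2.26 (SE 0.78) and 2.61 (SE 0.92), and CXCL2 at 1.75 (SE 0.98) within the 10 libraries. These values rest on low levels. CXCL2 had a median of 4.80 raw CPM in the 4 other libraries without MYH4 reads, against 0.717 in the 10. That is 0.470% of its level in midkine 3-2, and whether reads passed from midkine 3-2 add to it was not tested. The monocyte-attracting chemokines CCL2 and CCL7 had 4.35 (SE 1.35; 1.81 without midkine 3-2) and 3.55 (SE 1.00). CCL2 and CCL7 had 0.96 (SE 0.76) and 1.29 (SE 0.77) within the 10 libraries. All 11 class II antigen presentation genes were higher and 7 passed when adjusted over the list alone, CD74 at 1.37 (SE 0.56) and RT1-BA at 1.35 (SE 0.54). Both stood lower within the 10 libraries, at 0.21 (SE 0.41) and 0.22 (SE 0.40). Camera gave that list an adjusted p of 1.35e-04, and an estimated correlation gave an adjusted p = 0.424.

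Fibroblast and matrix genes were higher for all 19 measured members, with 3 past the threshold adjusted over the list alone and a mean level of 6.58 ± 0.89 and 7.66 ± 1.46 log2 CPM (adjusted p = 3.18e-07 by camera, adjusted p = 0.413 with an estimated correlation). DPT, BGN, MFAP5 and FAP, all products of fibroblasts, had log2 fold changes of 2.63 (SE 0.85), 1.41 (SE 0.46), 1.89 (SE 0.62) and 2.10 (SE 0.80). COL1A1 stood at 82114 CPM in midkine 5 and at 3606 CPM in the next midkine library. Without midkine 5 FAP stood at 1.10 (SE 0.56). The invasion list had 17 of 20 members higher and 4 past the threshold adjusted over the list alone (adjusted p = 4.78e-06 by camera, adjusted p = 0.413 with an estimated correlation). It includes VIM (0.94, SE 0.28), TGFBI (1.33, SE 0.35) and the collagenase gene MMP13 (3.77, SE 1.21). MMP13 had 2.03 without midkine 3-2 and 0.19 (SE 0.60) within the 10 libraries that carried MYH4 reads.

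Endothelial genes were higher for all 15 measured members, CLDN5 by a log2 fold change of 2.22 (SE 0.66), PECAM1 of 1.03 (SE 0.38) and ESAM of 0.81 (SE 0.30) (list adjusted p = 2.36e-06 by camera, adjusted p = 0.413 with an estimated correlation). Adipocyte genes were higher for 7 of 8 members, with CD36 at 3.07 (SE 0.94), FABP4 at 2.84 (SE 0.97) and PPARG at 1.17 (SE 0.47), and 2 passed when adjusted over the list alone (list adjusted p = 0.00190 by camera, adjusted p = 0.413 with an estimated correlation). The lowest values of CD36, FABP4 and PPARG in settings other than leaving out 1 library were 0.82, 0.11 and 0.43. All 5 measured erythroid genes were higher, HBA-A2 by 1.02 (SE 0.65) and ALAS2 by 1.06 (SE 0.62), or 2.04 and 2.12 without vehicle 5 (list adjusted p = 5.58e-04, and adjusted p = 0.413 with an estimated correlation). Hypoxia and glycolysis genes were higher for 17 of 20 members, among them PFKFB3 at 1.96 (SE 0.63), NDRG1 at 1.21 (SE 0.48) and ALDOA at 2.25 (SE 0.98) (list adjusted p = 0.0201, and adjusted p = 0.738 with an estimated correlation). ALDOA stood at 46662 CPM in midkine 1 and 2616 CPM in the next midkine library. Its value without midkine 1 was 0.17 (SE 0.31). That of NDRG1 without midkine 3-2 was 0.80 (SE 0.38).

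The lists that were lower in midkine tumours were epithelial for the most part. All 11 hormone-sensing luminal genes were lower, from 6.22 ± 0.52 log2 CPM in vehicle (SD, n = 6) to 5.49 ± 0.74 in midkine (SD, n = 9) (adjusted p = 1.80e-05 by camera, adjusted p = 0.413 with an estimated correlation). The estrogen receptor gene ESR1 had a log2 fold change of -0.85 (SE 0.42), the progesterone receptor gene PGR of -0.80 (SE 0.41), WNT4 of -0.99 (SE 0.44) and PROM1 of -0.74 (SE 0.41). Without vehicle 3 PGR had -0.50 (SE 0.42) and WNT4 -0.55 (SE 0.42). General epithelial genes were lower for 11 of 15 members (SPINT2 -0.47, SE 0.19; CLDN3 -0.47, SE 0.21), while KRT8 stood at 0.34 (SE 0.41) and, without midkine 4-3, at 0.02 (SE 0.34). That list had an adjusted p = 1.89e-04 by camera and an adjusted p = 0.424 with an estimated correlation. It stood at 8.32 ± 0.20 log2 CPM in vehicle and 7.97 ± 0.68 in midkine tumours, and midkine libraries lay on both sides of vehicle. Midkine 1 (7.03), 4-2 (7.21) and 5 (7.26) were the lowest. Midkine 3-2 (8.90) and 4-3 (8.79) lay above the highest vehicle library, vehicle 2-1 (8.55). Basal and myoepithelial genes were lower for 12 of 16 members, SOX10 at -0.55 (SE 0.27) and TP63 at -0.54 (SE 0.36; -0.26 without vehicle 6), against OXTR at 0.83 (SE 0.48) and KRT14 at 0.43 (SE 0.37; 0.26 without vehicle 2-1) (list adjusted p = 0.00635, and adjusted p = 0.450 with an estimated correlation).

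Fatty acid synthesis genes were lower for 14 of 20 members, at 6.40 ± 0.30 log2 CPM in vehicle and 6.08 ± 0.19 in midkine tumours (adjusted p = 0.00429 by camera, adjusted p = 0.413 with an estimated correlation). FASN, the fatty acid synthase, stood at 769 ± 553 and 429 ± 176 CPM (log2 fold change -0.84, SE 0.33, adjusted p = 0.431; -0.35, SE 0.25, without vehicle 6, which held 1878 CPM), ACLY at -0.50 (SE 0.18), ACACA at -0.39 (SE 0.24) and ACSS2 at 0.50 (SE 0.32), the last 2 at -0.23 and 0.81 without vehicle 3. SREBF1, the transcription factor that drives this pathway and a gene of interest to the study, stood at 269 ± 48.0 and 269 ± 131 CPM (log2 fold change 0.00, SE 0.27, adjusted p = 0.999). Interferon response genes were lower for 16 of 28 members, with OAS2 at -1.06 (SE 0.40), IRF7 at -0.70 (SE 0.28) and DDX58 at -0.51 (SE 0.23) against GBP5 at 1.30 (SE 0.52) (list adjusted p = 0.00935, and adjusted p = 0.713 with an estimated correlation).

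The immune lists differed less within the 10 libraries that carried MYH4 reads (6 vehicle, 4 midkine). The mean level difference there was -0.11 log2 for T and NK cells against 1.03 over all 15 libraries, 0.03 for class II against 0.79, 0.21 for inflammatory cytokines against 1.27 and 0.32 for macrophages against 0.84. It was 0.83 for fibroblasts against 1.09, 0.42 for vessels against 0.65 and 0.42 for invasion against 0.76. Adipocytes (0.98 against 0.92), erythroid genes (1.20 against 1.22) and hypoxia genes (0.59 against 0.38) differed by about as much or more. Of the lower lists, epithelium stood at -0.65 against -0.34, hormone-sensing cells at -0.84 against -0.73, basal cells at -0.29 against -0.35, fatty acid synthesis at -0.19 against -0.32 and interferon response at -0.69 against -0.21. With 1 of the 15 libraries left out, the difference over the rest was 0.77 for inflammatory cytokines without midkine 3-2, 0.65 for T and NK cells and 0.52 for class II without midkine 4-2, and 0.59 for hypoxia without vehicle 3. It was -0.10 without midkine 1 and -0.12 without vehicle 4 for interferon response, and without midkine 1 also -0.23 for epithelium and -0.23 for basal cells. By camera 10 lists passed within the 10 libraries, 7 higher and 3 lower, among them oxidative phosphorylation (adjusted p = 3.26e-10) and skeletal muscle (2.29e-08), which did not pass over 15 libraries. Without midkine 1 their mean level differences fell from 0.47 to 0.13 and from 2.89 to 0.78 log2, with adjusted p = 0.00240 and 0.00135 by camera. Over the 14 libraries other than midkine 1 both lists pointed down (0.0213 and 4.21e-05). The 10 libraries were kept for a muscle gene. The 5 midkine libraries left out had a muscle list mean of 2.12 log2 CPM, against 4.75 in vehicle. A rise of muscle within the 10 is thus partly set by that choice. Exact permutation of the mean level within the 10 libraries gave no list past the threshold (smallest adjusted p = 0.314). With 210 splits and 33 lists no single list could pass by itself, so this outcome says little about the lists.

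Midkine 5 set the size of the connective tissue differences within the 10 libraries. Without it the mean level difference was -0.16 log2 for fibroblasts, 0.02 for vessels and 0.05 for invasion. That of hormone-sensing cells was -0.44 and that of hypoxia 0.98. Without midkine 2 it was 1.71 for fibroblasts, 0.79 for vessels, 0.74 for invasion and 1.49 for adipocytes. Without midkine 1 it was 0.63 for invasion, 0.41 for adipocytes and 0.38 for hypoxia. Without midkine 6 it was 0.26 for invasion. Of the 10 calls there, invasion lost its own without vehicle 2-1 (adjusted p = 0.0733), 3 (0.194), 5 (0.0825) or 6 (0.0509) and without midkine 5 (0.786) or 6 (0.367). Fibroblasts lost theirs without vehicle 5 (0.0683) or midkine 5 (0.751). Adipocytes lost theirs without vehicle 3 (0.0589), 5 (0.0554) or 6 (0.0509) and without midkine 1 (0.364) or 5 (0.0959). Hypoxia lost its own without midkine 2 (0.0944) or 6 (0.0859). The other 6 calls were kept with any of the 10 libraries left out. All of these calls use the preset correlation. No estimated correlation was run within the 10 libraries, so the calls kept there do not account for genes that vary together.

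The small differences of the immune lists within the 10 libraries also hung on single libraries. Without midkine 6 class II stood at -0.34 log2 and passed downward (adjusted p = 0.0333), as did T and NK cells at -0.38 (0.0494), while inflammatory cytokines stood at -0.01 and macrophages at 0.11. Macrophages passed upward without vehicle 4 (0.52; adjusted p = 1.67e-04), midkine 1 (0.40; 0.0178) or midkine 5 (0.38; 0.0353), and stood at 0.21 without vehicle 2-1. Inflammatory cytokines stood at 0.45 without midkine 1, 0.35 without vehicle 5 and 0.13 without midkine 5. T and NK cells ranged from -0.38 to 0.13 and class II from -0.34 to 0.22 with 1 of the 10 left out. Basal cells stood at 0.06 without midkine 1, -0.65 without midkine 2 (adjusted p = 5.14e-04) and -0.13 without midkine 5, and passed without vehicle 2-1 (0.0409) or midkine 6 (0.0494) too. Fatty acid synthesis stood at -0.11 without vehicle 6 and -0.13 without vehicle 3, and vessels passed without vehicle 2-2 (0.00909), 4 (0.0107) or 5 (0.0485) and without midkine 1 (0.0162) or 2 (3.83e-04).

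Some calls rested on single libraries. The adjusted p for hypoxia was 0.0918 without vehicle 2-1, 0.15 without vehicle 2-2, 0.172 without vehicle 4 and 0.0510 without vehicle 6. It was 0.0609 without midkine 1, 0.124 without midkine 2, 0.155 without midkine 4-3 and 0.0924 without midkine 6. Interferon response lost its call without vehicle 4 (0.139), midkine 1 (0.264) or midkine 2 (0.0654), fatty acid synthesis without vehicle 3 (0.0910) and basal cells without midkine 1 (0.0609).

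**Figure D3:**
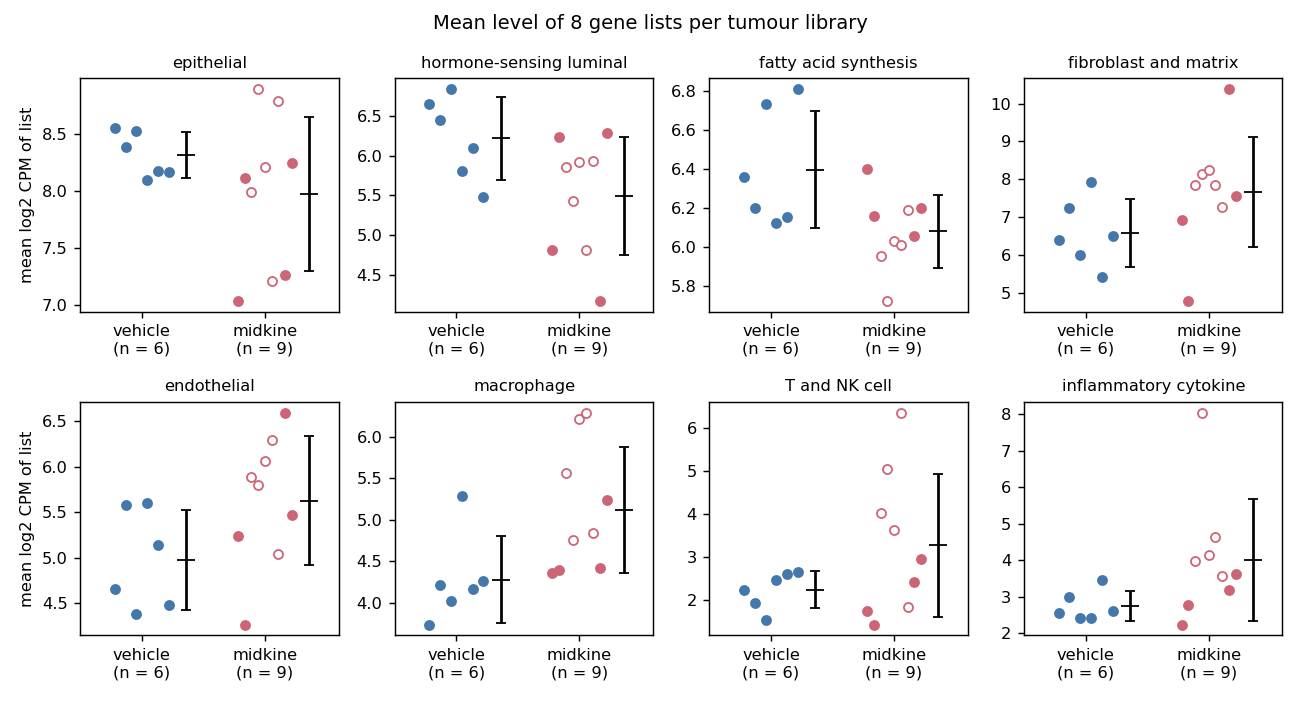
Mean log2 CPM of the measured members of 8 gene lists, per library, with blue points for vehicle (n = 6), red points for midkine (n = 9), open red points for midkine libraries with at most 1 MYH4 count, and bars for mean ± SD. The macrophage list lies at 4.28 ± 0.53 in vehicle and 5.12 ± 0.76 in midkine, and the highest T and NK cell values belong to open points.

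The remaining lists did not pass over 15 libraries. Proliferation genes had 25 of 34 members lower, with MKI67 at 159 ± 93.3 and 143 ± 85.7 CPM and CCNE2 at -0.33 (SE 0.23) (list adjusted p = 0.140). The list passed downward without vehicle 2-1 (0.00672) or 6 (7.27e-04) and without midkine 4-3 (0.0166), 5 (0.00689) or 6 (0.0150). Within the 10 libraries that carried MYH4 reads it passed upward by camera without midkine 1 (adjusted p = 3.12e-07) or vehicle 3 (0.0425). Skeletal muscle genes had a median log2 fold change of 6.29, all 18 past the threshold adjusted over the list alone, but a mean level difference of -0.18 log2 and an adjusted p of 0.964. Midkine 1 held the highest levels (MYH2 1431 CPM, DES 8065 CPM, ACTA1 59093 CPM) and midkine 5 the next (167, 173 and 1245 CPM). Without midkine 1 the log2 fold changes of these genes fell from 6.34 to 3.37, from 4.97 to 1.16 and from 5.49 to 0.57, and the list pointed down (adjusted p = 4.21e-05). Adjusted p-values were 0.260 for cholesterol synthesis (EBP -0.24, SE 0.25; list 0.00911 without vehicle 6 and 0.0121 without midkine 4-3), 0.309 for PI3K, AKT and mTOR components (PIK3CD 2.30, SE 0.73), 0.0558 for the ATF4 list (SLC7A11 3.73, SE 1.24, and 1.46 without midkine 3-2), 0.485 for oxidative phosphorylation (COX6C 0.37, SE 0.32, and 0.00 without midkine 1; list 0.00161 and up without midkine 3-2, 0.0213 and down without midkine 1) and 0.865 for ribosomal proteins (RPS23 0.16, SE 0.13). The ATF4 list passed without vehicle 3 (0.00609) or 5 (0.0107) and without midkine 1 (0.00427), 3-1 (0.0153), 4-1 (0.0320), 4-2 (0.0201) or 5 (0.0461).

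Adjusted p-values were 0.0730 for DNA repair (BRCA2 -0.33, SE 0.28), 0.862 for the p53 and senescence list (PLK2 -0.48, SE 0.26), 0.0903 for immune checkpoints (ICOS 3.00, SE 0.94), 0.0730 for milk secretion (CSN2 5.39, SE 2.10, and 0.95 without midkine 5; CSN3 -1.35, SE 0.61), 0.844 for mast cells (HDC 0.31, SE 0.68) and 0.839 for Schwann cells. DNA repair passed without vehicle 2-1 (0.0405), 2-2 (0.0305) or 6 (0.00389) and without midkine 4-1 (0.0498), 4-2 (0.0305), 4-3 (0.0302), 5 (0.0180) or 6 (0.0413). Milk secretion passed without vehicle 2-2 (0.0327) or 3 (6.93e-04) and without midkine 1 (0.0260), 3-1 (0.0461), 3-2 (0.0176), 4-2 (0.0469) or 5 (0.0103). Immune checkpoints passed without vehicle 5 (0.0380) or midkine 1 (0.0177) or 5 (0.00689). ICOS stood at 0.23 (SE 0.52) within the 10 libraries that carried MYH4 reads. With the epithelial level as a covariate the ATF4 list (8.58e-05), DNA repair (0.0441), milk secretion (6.42e-04) and immune checkpoints (0.00627) all passed.

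MAP kinase immediate early genes (DUSP1 1.63, SE 0.54; FOSL1 3.51, SE 1.29; 0.92 and 0.41 without midkine 3-2) had a median of 0.11 and a mean difference of 0.09 while camera pointed down (adjusted p = 0.981), and ribosomal genes had a median of -0.01 and a mean difference of 0.00 while camera pointed up. The mean difference of the MAP kinase list turned negative without midkine 3-2, which stood at 7.57 mean log2 CPM. Adjusted over the list alone, 1 immune checkpoint gene and 1 Schwann cell gene passed. Lists of B and plasma cells (3 genes; FCRLA 2.88, SE 1.12; FCMR 2.22, SE 0.89), neutrophils (2 genes; S100A9 1.91, SE 0.73) and keratinised epithelium (3 genes; CALML3 -0.67, SE 0.32) had too few measured members to test, with 2, 1 and 0 genes past the threshold adjusted over the list alone. The list of mitochondrially encoded genes had 0 measured members. PTPRC, the pan-leukocyte gene, stood at 26.0 ± 8.03 and 151 ± 255 CPM (2.54, SE 0.86), with 796 CPM in midkine 4-2 and a value of 1.45 (SE 0.58) without it, and its value within the 10 libraries that carried MYH4 reads was 0.08 (SE 0.27).

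Over all genes kept, treatment accounted for 9.17% of the squared expression distance between libraries (exact permutation p = 0.164 over all splits, one-sided). Midkine libraries lay farther from their group's mean profile than vehicle libraries, at 80.8 ± 29.3 (SD, n = 9) against 52.7 ± 9.95 (SD, n = 6) in units of log2 CPM distance, a difference of 28.2 (two-sided exact permutation p = 0.0384). Midkine 1 (132), midkine 3-2 (119), midkine 5 (89.8) and midkine 4-2 (85.6) were the farthest. With the correction for group size the difference was 28.0 and the exact permutation p = 0.0524. Without those 4 libraries the uncorrected difference was -4.02 (exact permutation p = 0.494).

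Within the 10 libraries that carried MYH4 reads the share was 14.6% (exact permutation p = 0.162) and the difference in spread 27.9 (exact permutation p = 0.00952), which fell to 8.43 without midkine 1 (exact permutation p = 0.345). The share there was 23.2% without midkine 2 (exact permutation p = 0.0595) and 20.6% without midkine 6 (0.0833). Of the fits that left out 1 of the 15 libraries, the one without midkine 2 gave a share of 11.8% (exact permutation p = 0.0400). In these fits the exact permutation p for the spread was over 0.05 without vehicle 2-1 (0.0644), 2-2 (0.0769), 4 (0.0539) or 5 (0.0504) and without midkine 1 (0.0932), 3-2 (0.0756), 4-2 (0.0679) or 5 (0.0776). No spread value in these fits or within the 10 libraries carries the correction for group size.

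**Figure D4:**
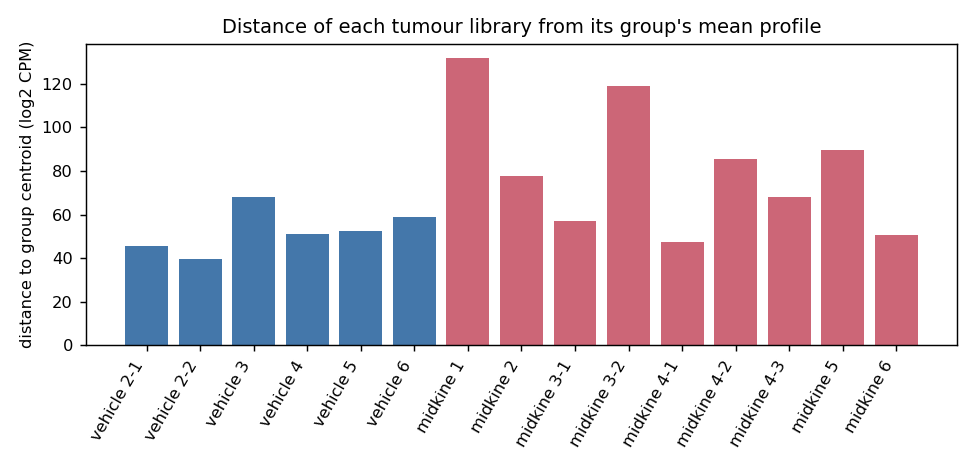
Euclidean distance in log2 CPM from each library to the mean profile of its own group, with 1 bar per library, blue for vehicle and red for midkine. Midkine 1 lies at 132 and midkine 3-2 at 119, while the vehicle libraries lie between 39.8 and 68.1.

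Libraries whose titles share a number were compared to learn whether they were alike. After group means were removed, the 5 such pairs had a mean correlation over genes of -0.0187 and the other 46 pairs within groups -0.136, a difference of 0.117 (one-sided permutation p = 0.175 over 100000 permutations). With 1 library left out the difference ran from 0.0252 without midkine 1 to 0.233 without midkine 3-2 (one-sided permutation p from 0.0644 to 0.422). It was under 0.06 without vehicle 2-1, vehicle 2-2 or midkine 4-1 (0.0572, 0.0575 and 0.0385) and over 0.2 without midkine 3-1 or 4-2 (0.217 and 0.228). The pair vehicle 2-1 and 2-2 had 0.217 and midkine 3-1 and 3-2 had -0.217. Midkine 4-1 had 0.10 with 4-2 and 0.175 with 4-3, and midkine 4-2 had -0.369 with 4-3. Over the 1000 most variable genes the difference was 0.260 (one-sided permutation p = 0.0460).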

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

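The tests of the list shift and of the MYH4 reads, the splits for genes past the threshold and the look at their members were chosen only after the result was seen, while the other splits and the muscle myosin tests were not. Single libraries lay far from the rest of their group in 74 of 304 sets of values checked, 68 times high and 6 times low, where chance gives about 1 in 20 for normally distributed values. CPM values are skewed to the high side and many genes were named for a large change, so that share is no measure of chance for these sets. Midkine 3-2 accounted for 19 of these and midkine 1 for 10. Values are CPM unless named otherwise.

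Midkine 3-2 stood apart at mean log2 CPM of 8.04 for inflammatory cytokines, 7.57 for MAP kinase immediate early genes, 7.34 for the ATF4 list, 6.16 for PI3K, AKT and mTOR components and, on the low side, 2.16 for erythroid genes. Its gene levels were CXCL2 1059, CXCL3 318, CCL2 719, CCL7 131, MMP13 821, FOSL1 505, DUSP1 332, SLC7A11 343, NCL 1319.6, ZEB2 70.0, MSR1 13.6, ICOS 74.5, ESR1 13.8 and, low, BRCA2 2.93. Midkine 4-2 was high in lymphocyte and macrophage genes: PTPRC 796, CD3G 215, PRF1 131, CD74 4105, LYZ2 1705, FCRLA 67.1, FCMR 187. It was also high in the ribosomal gene RPS23, 1236. Midkine 5 was high in the matrix genes COL1A1 82114, DPT 429, FAP 141, and in LRP1 1134, IGF1 128, SREBF1 578, MDK 674 and the casein gene CSN2 8276. Midkine 2 held LRP2 11.9, PROM1 149.5, SOX10 424. Midkine 3-1 held SDC2 187, and midkine 4-3 held ACLY 473.

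Among vehicle libraries, vehicle 4 stood at 5.28 mean log2 CPM of the macrophage list, with ZEB2 12.6, MSR1 4.78, COL1A1 5238, BGN 347, FAP 13.5 and a low PROM1 of 19.6. Vehicle 5 had the lowest total, 4.93 M counts, a p53 and senescence list at 6.53 mean log2 CPM, and ADORA2A 3.96, CXCL3 1.39, HBA-A2 234, ALAS2 9.12, S100A9 2.18. Vehicle 3 held SDC1 636, PGR 62.9, ACSS2 40.1, WNT4 125, EBP 44.9. Vehicle 6 held FASN 1878, TP63 317, vehicle 2-2 CD36 5.61, FABP4 40.2 and vehicle 2-1 PRSS8 206.

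Skeletal muscle transcripts filled midkine 1, where the muscle list held 27.2% of counts and stood at 14.01 mean log2 CPM, with ACTA1 59093, DES 8065, MYH2 1431, ALDOA 46662, COX6C 507, PFKFB3 178, GPC2 19.8, a low normalization factor of 0.558 and a low midkine ligand and receptor list at 5.65. Adult fibre myosins (MYH1, MYH2, MYH4, MYH7; the naming rule gives MYH2 alone) held 99.9% of its striated myosin counts, and embryonic and perinatal myosins (MYH3, MYH8, also outside the rule) 0.067%. The latter share argues against muscle-type differentiation of tumour cells, while muscle tissue in the sampled piece may account for the pattern.

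MYH4 reads stood at 72.5 to 167 raw CPM in 9 libraries and at no more than 0.167 in 5. Reads passed from midkine 1 within a sequencing pool would give every muscle gene 1 ratio to midkine 1: over 52 genes dominant there the median was 0.292%, and the upper quartile was 1.98 times the lower. In the 5 libraries the same median was 0.0647%, above the tenth that the pool explanation would allow, so it was met only in part. Muscle tissue in each tumour piece remains open too, since MYH4 ranged over only 2.30 times in the 9 libraries but the bound was set once these levels were known. These explanations cannot be told apart here, as no label gives a pool.

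Lists of connective tissue, vessel and immune cells were higher and epithelial lists lower in midkine libraries. A lower share of epithelial cells would raise all other cell types alike. The 8 such lists were all higher, by 0.14 to 1.22 log2, a range of 1.08 (1.30 within the 10 libraries that carried MYH4 reads). The bound was the largest vehicle SD, 1.52, which is that of mast cells, against 0.53 for macrophages and 0.22 for Schwann cells. A bound set by the most variable list can hardly go against the explanation, so this outcome says little. With the epithelial level as a covariate, a test chosen after the first was seen, the median ratio of adjusted to unadjusted differences was 0.920 (0.629 to 1.33). That ratio went against this explanation, but the adjusted differences had standard errors nearly as large as themselves for several lists, so it stays open. A technical difference of the 5 libraries without MYH4 reads may contribute. The median ratio of the immune differences within the 10 other libraries to those over 15 was 0.104. With 1 library left out it ran from -0.181 without midkine 6 to 0.265 without midkine 1. Yet the 5 are all midkine libraries of title numbers 3 and 4, and a treatment effect stays open as untested.

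Chance was not excluded for the count of genes at an unadjusted p under 0.05, of lists or of DESeq2 calls. Of 100 splits of the libraries into 6 and 9, the real one included, 15 gave as many genes at an unadjusted p (real 1178, highest other 2419). As many lists came from 32 of them (real 15, highest other 20). With DESeq2, 4 of 25 splits, the real one included, called as many genes (real 92, highest other 451). The counts of 0 genes higher and 0 lower could not be tested in this way, since all 100 splits give at least 0 (highest other 1 higher and 247 lower). A single split gave the 247 and the 451, and 1 other called 192 lower. These point to a structure of the samples that stays open. With edgeR no other split called a gene, and both belong to the 3 splits that put 4 of the 5 libraries without MYH4 reads into the group of 6. The third of these called 0, and the 2 share 5 of their 6 members (midkine 3-1, 3-2, 4-1, 4-2 and 6), so they count for little more than 1. Among midkine libraries, edgeR called 0 genes higher and 0 lower in the 5 without MYH4 reads than in the 4 with them (1262 at an unadjusted p under 0.05). MYH4, which sets these libraries apart, was not called either, so the 0 cannot show that they are alike.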

How the results depend on the processing

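The settings with only the 10 libraries that carried MYH4 reads, without the 4 libraries that stand apart, with MYH4 carriage, with the epithelial level for lists, DESeq2 without outlier replacement and the group-size correction were chosen only after the result was seen. The count of 0 genes held in every edgeR and limma-voom setting run, while DESeq2 called 86 higher and 6 lower, or 79 and 5 without outlier replacement. Of the 169 genes of the naming rule, 121 kept their direction in every setting, 48 turned in at least 1, and 29 passed in at least 1, all by DESeq2. The list count was 15 at the preset correlation, 0 with an estimated correlation and 0 with fry. At the preset correlation it ranged from 13 to 20 with 1 library left out. All libraries without MYH4 reads are midkine libraries, so group differences with MYH4 carriage come from the 10 libraries again and are no separate check. The cause of the changes below was not tested. Depth limits the precision of genes with few counts.

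Genes at an unadjusted p under 0.05 numbered 602 with limma-voom, 599 with the title-number correlation (consensus 0.00238), 745 with the first library of each number, 323 with the number as a block and 760 without the 4 libraries apart, against 1178. The highest count among such settings was 1670, and with 1 library left out the count ran from 794 to 1437. Vehicle and midkine libraries with the same number correlated at r of -0.236 to 0.139, and 0 of 5 numbers had its own number as best partner. The values with the block thus rest on a pairing that neither the labels nor these correlations bear out. Without the 4 libraries the difference in spread was -4.02 (exact permutation p = 0.494), with the group-size correction 28.0 (0.0524), and with 1 library left out 19.6 to 33.6. The treatment share ranged from 8.09% to 11.9% with 1 library left out, and similarity over the 1000 most variable genes was 0.260.

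Directions of genes turned as follows, in log2 fold change. SREBF1 stood at -0.021 with upper-quartile scaling, -0.0086 without a filter, -0.11 with voom, -0.076 with quality weights, -0.11 with the title-number correlation, -0.038 with the block, -0.14 with the epithelial level, -0.055 with a surrogate variable and -0.10 without the 4 libraries. In the same order where they turned, MDK stood at -0.073 with voom, -0.073 with the correlation and -0.18 with the epithelial level. ACTA1 stood at -0.29, -0.61 and -0.29 with the 3 voom fits, -0.69 with the block, -1.37 with the epithelial level and -0.55 without the 4 libraries. Quality weights turned ITGA4 (-0.14), MKI67 (0.21) and EBP (0.085). LTK was -0.15 with summed counts and -0.016 with a surrogate variable. The first library of each number turned SDC1 (-0.036), NCL (-0.047) and KRT8 (-0.14), and the epithelial level turned SDC4 (0.11). Without the 4 libraries SDC4 was 0.034, ITGA4 -0.49, ITGA6 0.068, NOTCH2 -0.086, MKI67 0.047, CSN2 -0.95 and EBP 0.086. Within the 10 libraries LTK was -0.41, ITGB1 -0.016, MKI67 0.14, KRT8 -0.27, SLC7A11 -0.19 and FCRLA -0.084. With MYH4 carriage they were -0.43, -0.026, 0.12, -0.28, -0.20 and -0.095, and SDC1 was -0.0027. With 1 library left out MDK ranged from -0.32 to 0.21, ALK from -0.67 to 0.052, LTK from -0.18 to 0.66, LRP2 from -0.11 to 0.40, MKI67 from -0.38 to 0.076 and SREBF1 from -0.22 to 0.095.

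Calls of lists ended, in adjusted p, without the 4 libraries for epithelium (0.377), hormone-sensing cells (0.175), adipocytes (0.355) and interferon response (0.317), and for basal cells with a turn of direction (0.614). They ended within the 10 libraries for fatty acid synthesis (0.199), inflammatory cytokines (0.747), class II (0.873), basal cells (0.0981), vessels (0.0603), macrophages (0.0754) and, with a turn, T and NK cells (0.752), and with MYH4 carriage for fatty acid synthesis (0.141), inflammatory cytokines (0.711), class II (0.923), basal cells (0.110), macrophages (0.108) and, with a turn, T and NK cells (0.823). With the block they ended for hypoxia (0.0581) and basal cells (0.123), and with the epithelial level for interferon response (0.260) and basal cells (0.209). The epithelium call also ended there (0.983), but that list's own mean was the covariate, so this outcome was fixed in advance. Lists that passed only in an alternative were the ATF4 list with the block (0.00996) and the epithelial level (8.58e-05), DNA repair with summed counts (0.0360) and the epithelial level (0.0441), milk secretion with the epithelial level (6.42e-04) and without the 4 libraries (7.57e-05), immune checkpoints likewise (0.00627 and 0.0443), ribosomal genes (8.68e-04) and, turned up, proliferation (0.00374) without the 4 libraries, and MAP kinase genes, turned up, with the epithelial level (0.00675). Oxidative phosphorylation passed upward with summed counts (0.0331), without the 4 libraries (0.0443), within the 10 libraries (3.26e-10) and with MYH4 carriage (5.28e-11), and muscle in the last 2 (2.29e-08 and 2.27e-12). Both of these last settings were set by a muscle gene, so the result for muscle is not independent of them. Downward, oxidative phosphorylation passed with the block (0.0345), and muscle with the block (3.33e-04), with the epithelial level (0.00321) and without the 4 libraries (3.03e-11). Over single libraries left out, adjusted p ranged from 0.00427 to 0.628 for the ATF4 list, 0.00389 to 0.804 for DNA repair, 6.93e-04 to 0.629 for milk secretion and 0.00689 to 0.719 for immune checkpoints.

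Directions of lists turned as follows, in adjusted p. Relative log expression scaling turned skeletal muscle (0.899), fry turned MAP kinase genes (0.969), and summed counts turned p53 (0.826) and ribosomal genes (0.548). The block turned midkine ligands (0.610), MAP kinase genes (0.600), oxidative phosphorylation and muscle (both above). The epithelial level turned midkine ligands (0.413), cholesterol synthesis (0.261), oxidative phosphorylation (0.110), and MAP kinase genes and muscle (both above). Leaving out the 4 libraries turned midkine ligands (0.377), cholesterol synthesis (0.317), PI3K components (0.185), MAP kinase genes (0.377), DNA repair (0.403) and Schwann cells (0.284), and proliferation, basal cells and muscle (above). The 10 libraries turned proliferation (0.752), p53 (0.541), immune checkpoints (0.0785), mast cells (0.948) and Schwann cells (0.690), and MYH4 carriage turned proliferation (0.782), p53 (0.487) and immune checkpoints (0.120). With 1 library left out, adjusted p ranged from 0.345 to 0.869 for midkine ligands, 0.00911 to 0.858 for cholesterol synthesis, 7.27e-04 to 0.983 for proliferation, 0.133 to 0.997 for PI3K components, 0.0776 to 0.996 for MAP kinase genes, 0.00161 to 0.940 for oxidative phosphorylation, 0.179 to 0.996 for p53, 0.128 to 0.986 for ribosomal genes, 4.21e-05 to 0.996 for muscle, 0.191 to 0.997 for mast cells and 0.518 to 0.997 for Schwann cells.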

Other observations

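The tests below were chosen only after the result was seen, and the genes named from single libraries (except CSN2), TTR, AHSG, APOA1 and APOA2 lie outside the naming rule and were chosen after their values were seen. Midkine 3-2 held 2643 CPM of the chemokine gene CXCL1 against a vehicle mean of 7.16, 4011 CPM of the urokinase gene PLAU against 20.4, 184 CPM of the nitric oxide synthase gene NOS2 against 1.17 and 179 CPM of the cytokine gene LIF against 1.27. Midkine 4-2 held 1549 CPM of the lymphoid chemokine gene CCL21 against 16.9, 220 CPM of the B cell gene CD22 against 3.05, 675 CPM of IGF2 against 1.66 and 199.9 CPM of the macrophage gene SIGLEC1 against 4.85. Midkine 5 held 44905 CPM of the collagen gene COL3A1 against 954 and 8276 CPM of the casein gene CSN2 against 22.8.

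Interferon response genes were lower within the 10 libraries that carried MYH4 reads, by -0.69 log2 in mean level (two-sided exact permutation p = 0.00952, adjusted p = 0.314 over 33 lists). With 210 splits no single list could pass that adjustment by itself. OAS2 stood there at -1.92 (SE 0.31) and IRF7 at -1.34 (SE 0.23). ALB and FGB, genes of liver secretion, ranged from 12.5 to 30.9 and from 45.5 to 105 raw CPM over all 15 libraries, while TTR reached no more than 0.908, AHSG 0.756, APOA1 3.25 and APOA2 0.422.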
